A study of Mus musculus with 22 samples.

How the data were processed

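RNA was measured by sequencing in 22 bulk tissue libraries from the striatum of adult male C57BL/6J mice. Mice that had self-administered oxycodone, at 0.25 mg/kg per infusion in daily sessions of 4 h over 14 days, were set against yoked mice that received saline. Ventral striatum gave 6 oxycodone and 6 saline libraries, and dorsal striatum gave 5 and 5. The labels name column-purified total RNA and a stranded library kit that removes ribosomal RNA. They place 8 ventral libraries in lane 1 and 4 in lane 2, each lane evenly split between treatments. Titles of 5 dorsal libraries carry the suffix P, whose meaning is not given, and 2 pairs of dorsal libraries share a title number and a treatment.

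The deposited table holds raw counts for 23119 Ensembl genes in the 22 libraries. Per the labels, the authors used CASAVA 1.8.2, STAR 2.3 and featureCounts, for which no version is stated. They name the builds mm10, GRCm38 and mm9 without saying which step used which, and they do not state the strand setting, the treatment of multi-mapping reads, or whether read mates were counted singly. Every value in the table was a whole number, and no column was left without a sample. Symbols and positions were taken from GENCODE M21 on GRCm38, by gene identifier, for 22205 of the identifiers (96%). Gene names and positions are therefore those of that release and not necessarily of the annotation used for counting.

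Library totals ran from 8408829 to 11000345 counts in the ventral libraries and from 11314079 to 21921963 in the dorsal ones. At these depths a gene with 0 counts in a library is limited to 3 counts of its total, and such limits cover counting error only. Pairs of libraries within a group were checked for repeated sequencing of 1 library by a chi-square per degree of freedom on genes with at least 100 summed counts. The lowest value of any pair was 2.88, against about 1 for a pure repeat, so each library was kept as its own sample.

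Oxycodone was compared with saline within each region by the edgeR quasi-likelihood test with robust dispersions (edgeR 4.0.16 in R 4.3.3), on counts scaled by TMM factors, for genes kept by filterByExpr. A contrast over all 22 libraries in 4 groups tested whether the oxycodone effect differed between regions, and a fit of the 11 saline libraries compared dorsal with ventral striatum. P values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. All tests were two-sided. Fold changes are on the log2 scale with their standard errors (SE), and group levels are means of TMM-scaled CPM (counts relative to the library total) with standard deviations (SD).

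Gene lists for cell types, receptors, signalling and stress responses were fixed before the data were examined, together with the comparisons, the tests and most of the alternatives. They hold 706 distinct genes, of which 695 are in the table. The 31 lists with at least 5 tested members, sex check genes apart, were tested in each region by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists within a region. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move, on balance, one way. The level of a list in a library is the mean of its members' log2 CPM, with a prior count of 2. Fold changes of the 2 regions were correlated across genes tested in both, beside 100 permutations of the treatment labels within each region.

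Genes to be named were set by a rule fixed at the same time. For each oxycodone comparison it takes the 8 largest rises and 8 largest falls past the threshold at a mean of at least 1 CPM, filled up to 16 by the lowest unadjusted p. It adds up to 3 members of each list with the lowest unadjusted p, and always the opioid receptor genes, Penk, Pdyn, Fos, Drd1 and Drd2. For the difference between regions it takes 8 genes, and for the saline libraries the 8 largest changes each way and up to 4 members of each of 3 marker lists. Unnamed gene models are passed over. The rule covers more genes than are given here: the ones printed are a subset of it picked after their values had been seen. Genes outside the rule, Gh and Slc17a7 among them, are marked as chosen after their values were seen.

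Alternatives were other scaling factors (DESeq2's median of ratios, upper quartile, library totals), other filters, DESeq2 1.42.0 and limma-voom with quality weights, dispersions without robust estimation, a threshold of 0.1, 1 surrogate variable (sva 3.50.0), lane or title suffix as a covariate or as a subset, summed pairs, all libraries in 1 fit, title number as a block, and leaving out each replicate in turn. After the data had been seen, 5 more were added: leaving out 2 ventral libraries that stand apart, halving the dorsal counts, the haemoglobin level as a covariate, a fold of at least 2 between regions, and a fit without the block on the libraries the block uses. Other splits of the same libraries, 100 with the real one included, were fitted in the same way. The fits were tested on simulated data made from the same tables, in which 200 genes were changed. Of those changed 2-fold, the test recovered 76.1% in the ventral design, 70.1% in the dorsal one, 52.2% for the difference and 67.2% for the saline regions. Unchanged genes called beside them were 10, 8, 9 and 7, in the same order. Simulated genes varied independently and no library stood apart across genes, so these shares need not hold for the real libraries. No library was left out of the comparisons as designed.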

Results

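Transcript counts were compared between mice that had self-administered oxycodone, an opioid analgesic, and yoked mice that received saline, separately in ventral and dorsal striatum. The ventral striatum was represented by 6 oxycodone libraries of 8408829 to 10007992 counts and 6 saline libraries of 9172185 to 11000345 counts. In the dorsal striatum, 5 oxycodone libraries held 13797075 to 17836414 counts and 5 saline libraries 11314079 to 21921963. Between 16977 and 17365 genes had at least 1 count in a ventral library, and between 15622 and 16817 in a dorsal one. Mitochondrial genes took 5.98% to 9.25% of the counts in ventral libraries and 2.93% to 4.12% in dorsal ones.

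Marker genes set 2 ventral libraries apart from the other 10. Markers of the ventral striatum had a mean level of 5.5 log2 CPM in the other 10 libraries, 3.74 in oxycodone replicate 6 and 2.59 in saline replicate 6, while the 10 dorsal libraries averaged 3.52. In saline replicate 6, markers of D1 medium spiny neurons, the striatal projection neurons that carry the D1 dopamine receptor, stood at 2.78 log2 CPM against 5.71 in the other 10, and markers of glutamatergic neurons at 5.84 against 4.11. Oxycodone replicate 6 had choroid plexus and ependyma markers at 3.7 log2 CPM against 1.37 in the other 10, and dorsal striatum markers at 7.21 against 6.31. Both libraries remain in the comparisons as designed, and the counts of genes and the calls of lists without them are given with the ventral results.

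**Figure D1:**
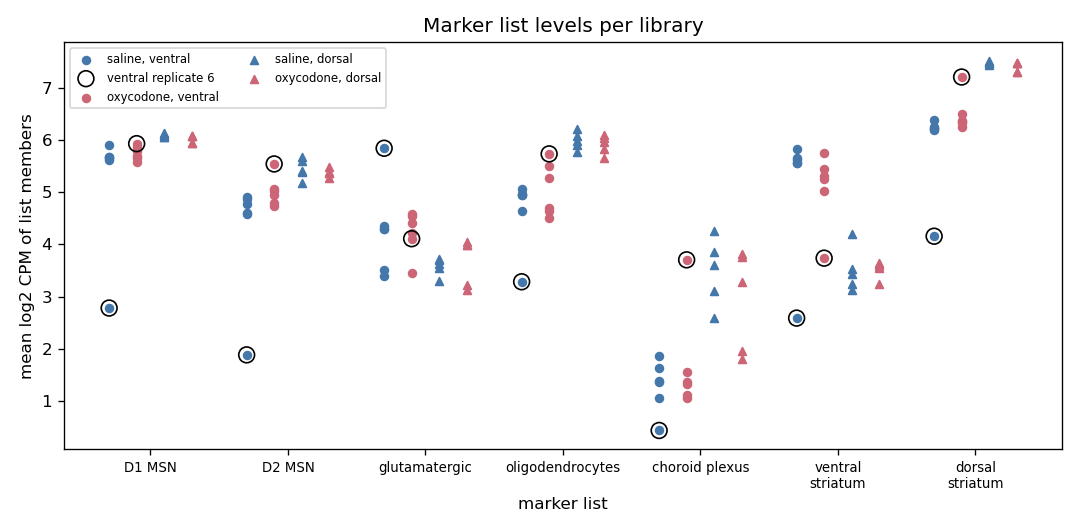
Mean log2 CPM of marker gene lists (vertical axis) in each of the 22 libraries, by group, each point standing for 1 library. On the ventral striatum list the sixth ventral library of each group lies below the other 10 ventral libraries, at 3.74 for oxycodone and 2.59 for saline.

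The dorsal striatum comparison asked which transcripts differ after oxycodone self-administration in the region of the caudate and putamen. Of 14595 genes, 30 passed the adjusted threshold, 29 of them higher and 1 lower after oxycodone. Xdh, which encodes the purine-degrading enzyme xanthine dehydrogenase (ENSMUSG00000024066, GRCm38 chromosome 17, 73883895 to 73950196), went from 45.5 ± 4.11 to 82.5 ± 14.8 CPM (SD, n = 5 and 5), a log2 change of 0.86 with SE 0.12 and an edgeR adjusted p of 0.000593. All 5 oxycodone libraries exceeded all 5 saline libraries for Xdh. Cp, which encodes the copper-carrying ferroxidase ceruloplasmin (ENSMUSG00000003617, chromosome 3, 19957054 to 20009145), rose by 0.68 on the log2 scale with SE 0.11 and an adjusted p of 0.00502, again with all 5 libraries above all saline ones. Tgm2, which encodes transglutaminase 2 (ENSMUSG00000037820, chromosome 2, 158116402 to 158146436), rose by 0.95 with SE 0.16 and an adjusted p of 0.0101, from 30.3 ± 2.65 to 58.4 ± 19.1 CPM. Slc2a1, the glucose transporter of the blood-brain barrier, rose 1.5-fold, with 4 of 5 oxycodone libraries above every saline library and an adjusted p of 0.0162, and it passed in 6 of the 10 fits that each left out 1 library.

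Some of the genes that rose in the dorsal striatum are known from white blood cells and microglia. Fcgr4, an Fc receptor for immunoglobulin G, rose 4.63-fold from 1.65 ± 0.785 CPM (SD, n = 5). Fpr2, a receptor for formylated peptides, rose 4.55-fold, and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose 4.09-fold. Itgal and Itgb2, which encode the chains of the leukocyte integrin LFA-1, rose 4.39-fold and 2.1-fold. Ptprc, which encodes the pan-leukocyte protein CD45, rose 2.09-fold. For these 6 genes all 5 oxycodone libraries lay above all 5 saline ones. Plac8 also rose, by 4.34-fold. Adjusted p in the edgeR fit was 0.0162 for Fcgr4, Itgal and Cybb, 0.034 for Fpr2, 0.0439 for Itgb2, and 0.015 for Ptprc and Plac8. Of the 10 fits that each left out 1 library, Itgb2 passed in 2, Fpr2 in 3, Fcgr4 and Itgal in 6, and Cybb, Ptprc and Plac8 in 7.

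Irf1, Tgtp1 and Ube2l6 rose as well. Irf1, an interferon-induced transcription factor (ENSMUSG00000018899, chromosome 11, 53770014 to 53778374), went from 8.62 ± 0.758 to 29.2 ± 15.7 CPM (SD, n = 5 and 5), a 3.37-fold rise with an edgeR adjusted p of 0.0162. Tgtp1, an interferon-induced GTPase with a near-identical neighbouring copy, rose 3.56-fold, and Ube2l6, which conjugates the interferon-induced modifier ISG15, rose 3.79-fold. Their adjusted p values were 0.0162 and 0.0209, and 4 of 5 oxycodone libraries exceeded every saline library for each. Psmb8 and Psmb9, subunits of the immunoproteasome that makes peptides for antigen presentation, rose 2.51-fold and 2.81-fold, each with an adjusted p of 0.0391. Of the 10 fits that each left out 1 library, Irf1, Ube2l6 and Psmb8 passed in 4, Tgtp1 in 5 and Psmb9 in 3. Psmb8 and Psmb9 were the 2 members past the all-gene threshold among the 27 tested on the list for complement and antigen presentation, of which 13 passed when adjusted over the list alone, all higher. The list had a median log2 change of 1.03 and shifted up by camera, with an adjusted p of 1.39e-25. With an estimated correlation its adjusted p was 0.175. Ifitm3, on the same list, had a log2 change of 1.12 with SE 0.26 and an adjusted p of 0.0621.

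The list of genes that respond to glucocorticoids shifted up by camera in the dorsal striatum, with an adjusted p of 1.65e-21, and was not called with an estimated correlation, at 0.112. Zbtb16, a transcription factor induced by glucocorticoids (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), rose from 24.7 ± 6.57 to 46.4 ± 7.95 CPM (SD, n = 5 and 5), with a log2 change of 0.91, SE 0.17 and an edgeR adjusted p of 0.0162. It passed in 6 of the 10 fits that each left out 1 library. It was the only one of the list's 20 tested members past the all-gene threshold, and 4 passed when adjusted over the list alone, all higher. All 20 had a positive log2 change, with a median of 0.55. Lcn2, the iron-binding protein lipocalin 2, stood at 11.6 ± 6.05 CPM in saline and 38.6 ± 14 CPM in oxycodone libraries, with an adjusted p of 0.269. Sult1a1, a sulfotransferase, had a log2 change of 0.61 with SE 0.18 and an adjusted p of 0.271.

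The list of blood transcripts shifted up by camera in the same libraries, with an adjusted p of 3.51e-11, and was not called with an estimated correlation, at 0.0662. Alas2, the haem synthesis enzyme of red cell precursors, rose 1.69-fold with an edgeR adjusted p of 0.0197 and all 5 oxycodone libraries above all saline ones, and passed in 6 of the 10 fits that each left out 1 library. The blood list had 11 tested members, 6 of them past the threshold when adjusted over the list alone, and a median log2 change of 0.76. Hbb-bs, a haemoglobin gene, stood at 338 ± 68.2 CPM in saline and 750.2 ± 309 CPM in oxycodone libraries (SD, n = 5 and 5), with an adjusted p of 0.402. With the haemoglobin level as a covariate, added after the data had been seen, 2 genes passed the threshold, both lower, and 0 of them were among the 30.

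Other lists moved by smaller amounts in the dorsal striatum. The list of cytokines, chemokines and their receptors had 9 of 53 members past the threshold when adjusted over the list alone, all higher, a median log2 change of 0.22 and a camera adjusted p of 1.47e-07, or 0.256 with an estimated correlation. Il1b, the cytokine interleukin-1 beta, had a log2 change of 2.95 with SE 0.72 and an edgeR adjusted p of 0.0912, and 1.93 with an adjusted p of 0.986 without oxycodone replicate 5, which held 13.2 CPM against 3 in the next oxycodone library. The microglia list, with 2 of 20 members past the threshold when adjusted over the list alone, had a median of 0.22, a camera adjusted p of 0.00013 and an adjusted p of 0.256 with an estimated correlation. Csf1r, the growth factor receptor of microglia, had a log2 change of 0.25 with SE 0.08 and an adjusted p of 0.413. Integrins had 2 of 23 members past the all-gene threshold, and over the list alone 4 higher and 1 lower; the list's camera adjusted p was 0.0018, or 0.256 with an estimated correlation. Heat shock and chaperone genes had a median of 0.12 and a camera adjusted p of 0.0333, or 0.647 with an estimated correlation, and 0 of 25 members passed over the list alone.

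Lists that shifted down by camera in the dorsal striatum were choroid plexus and ependyma, dorsal striatum markers, and GABA and glycine receptors. Their adjusted p values were 0.000136, 0.0145 and 0.027, and with an estimated correlation none was called, at 0.397, 0.313 and 0.256. Their median log2 changes were -0.35, -0.09 and -0.08, and 0 members of any passed the threshold when adjusted over the list alone. Cnr1, the cannabinoid CB1 receptor gene, had a log2 change of -0.3 with SE 0.11 and an edgeR adjusted p of 0.637. The 1 gene that fell past the all-gene threshold was Sh3rf2, from 89.7 ± 8.25 to 65 ± 7.41 CPM, with an adjusted p of 0.0475 and all 5 oxycodone libraries below all saline ones. It passed in 2 of the 10 fits that each left out 1 library, and its adjusted p was 0.057 with upper quartile factors, 0.0569 on library totals and 0.0851 by limma-voom.

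The dorsal count rested on single libraries. Without saline replicate 5 only 1 gene passed, 1 of the 30, and without oxycodone replicate 2 there were 9, of which 8 were among the 30, while without oxycodone replicate 3 there were 63, all 30 among them. Xdh passed in all 10 fits that left out 1 library, Cp and Tgm2 in 9 and Irf1 in 4. In libraries without the title suffix P (2 oxycodone, 3 saline) 17 genes passed, 3 of them among the 30, and in those with it (3 and 2) 1 passed, also among the 30. With the 2 pairs of libraries that share a title number summed, 40 genes passed, 24 of them among the 30.

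**Figure D2:**
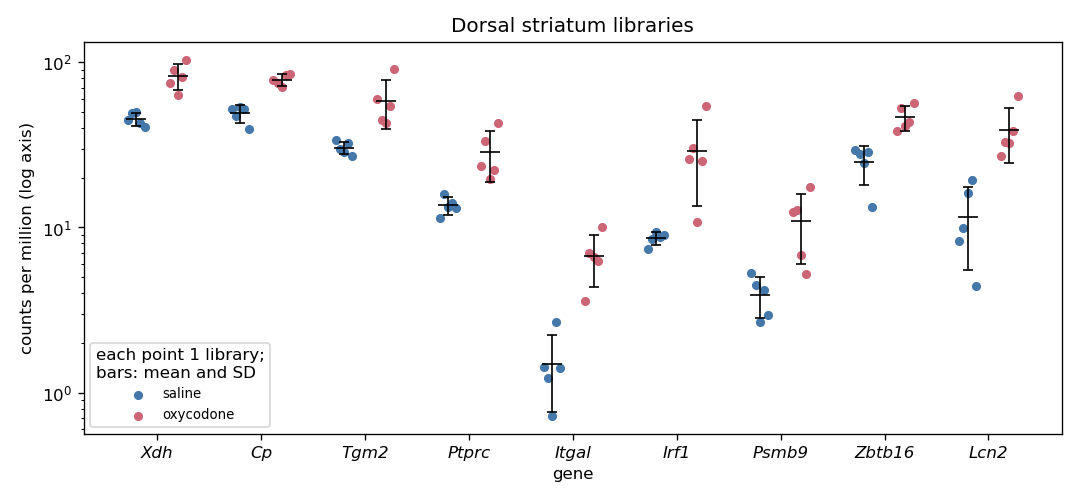
CPM on a log axis of genes named for the dorsal striatum, all but Lcn2 past the adjusted threshold, with each point 1 library and the bar the group mean, for 5 saline and 5 oxycodone libraries. For Xdh, the 5 saline libraries lie at or below 49.7 CPM and the 5 oxycodone libraries at or above 63.7 CPM.

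The ventral striatum comparison put the same question to the region that holds the nucleus accumbens. No gene passed the adjusted threshold in the edgeR fit of 14116 genes, where the smallest adjusted p was 0.237, and 1289 genes had an unadjusted p under 0.05 against 706 expected. DESeq2 called 43 genes and limma-voom with quality weights 61, with 25 called by both. The 2 genes with the lowest p are on the heat shock and chaperone list. Hspa5, the main chaperone of the endoplasmic reticulum (ENSMUSG00000026864, GRCm38 chromosome 2, 34771970 to 34777547), stood at 281 ± 29.2 CPM in saline and 469 ± 88.8 CPM in oxycodone libraries (SD, n = 6 and 6), with a log2 change of 0.74, SE 0.12 and an edgeR adjusted p of 0.237. Xbp1, a transcription factor of the unfolded protein response (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893), had a log2 change of 0.56 with SE 0.09 and the same adjusted p. All 6 oxycodone libraries lay above all 6 saline libraries for Hspa5 and for Xbp1, and DESeq2 and limma-voom called both, with adjusted p values of 0.000133 and 0.02 for Hspa5 and 3e-04 and 0.0176 for Xbp1.

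The list of heat shock and chaperone genes shifted up by camera in the ventral striatum, with an adjusted p of 8.97e-20, and was not called with an estimated correlation, at 0.583, the members' estimated correlation being 0.552. All 25 tested members had a positive log2 change, with a median of 0.4, and 18 passed the threshold when adjusted over the list alone, against 0 over all genes. Pdia4, a disulfide isomerase of the endoplasmic reticulum, had 91.9 ± 4.78 CPM in saline and 145 ± 31.1 CPM in oxycodone libraries (SD, n = 6 and 6), and Sdf2l1, a component of the same chaperone complexes, had 4.48 ± 0.959 and 8.86 ± 2.34 CPM. Both had an edgeR adjusted p of 0.262 and were called by DESeq2 and limma-voom. In oxycodone replicate 6, 10 of the 25 members were higher than in every other ventral library, and in saline replicate 6, 8 were lower than in every other. Without these 2 libraries the camera adjusted p of the list was 6.19e-18, and 0.339 with an estimated correlation.

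Prl and Gh, which encode pituitary hormones, had higher mean levels in ventral oxycodone libraries and did not pass the threshold of the edgeR fit. Prl, prolactin, had 0.752 ± 0.355 CPM in saline and 2.58 ± 1.11 CPM in oxycodone libraries (SD, n = 6 and 6), with an edgeR adjusted p of 0.262. Gh, growth hormone, chosen after its values were seen, had 4.2 ± 2.19 and 21.7 ± 15.4 CPM with an adjusted p of 0.303 and all 6 oxycodone libraries above all 6 saline ones. DESeq2 and limma-voom called both genes.

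Among genes with lower levels after oxycodone, Neb, which encodes the muscle filament protein nebulin, had 20.1 ± 2.3 CPM in saline and 11.4 ± 2.66 CPM in oxycodone libraries (SD, n = 6 and 6), and Armcx5 had 45.1 ± 5.35 and 32.6 ± 1.99 CPM. Their edgeR adjusted p was 0.262, and both were called by DESeq2 and limma-voom, with all 6 oxycodone libraries below all saline ones. Ercc3, a DNA helicase of transcription and nucleotide excision repair, had a log2 change of -0.26 with SE 0.05 and an edgeR adjusted p of 0.262. DESeq2 called it, with an adjusted p of 0.0196, and limma-voom did not, with 0.0539.

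Camera also called immune and glucocorticoid-responsive lists higher in the ventral striatum, none of them with an estimated correlation. The glucocorticoid list had a median log2 change of 0.3 with all 20 members positive, a camera adjusted p of 2.58e-05 and 0.651 with an estimated correlation. Complement and antigen presentation had a median of 0.45, a camera adjusted p of 0.000103 and 0.735 with an estimated correlation. For microglia and for cytokines the medians were 0.2 and 0.08, the camera adjusted p values 0.000355 and 0.0488, and the adjusted p values with an estimated correlation 0.708 and 0.798. Without both sixth libraries the camera adjusted p values, each followed by that with an estimated correlation in parentheses, were 1.62e-05 (0.383) for the glucocorticoid list, 7.64e-06 (0.435) for complement and antigen presentation, 7.64e-06 (0.346) for microglia and 2.01e-05 (0.346) for cytokines. In each of these 4 lists 0 members passed when adjusted over the list alone. Tsc22d3, a glucocorticoid-induced leucine zipper gene, had a log2 change of 0.52 with SE 0.16 and an edgeR adjusted p of 0.401. C5ar1, a complement receptor gene, had 1.36 with SE 0.41 and an edgeR adjusted p of 0.393. It was called by limma-voom, with an adjusted p of 0.0466, and not by DESeq2, with 0.185.

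Camera called 3 further lists of region and cell type markers in the ventral comparison, none of them with an estimated correlation. Dorsal striatum markers, oligodendrocytes and D2 medium spiny neurons had medians of 0.55, 0.42 and 0.4, camera adjusted p values of 8.72e-05, 0.000355 and 0.00722, and adjusted p values with an estimated correlation of 0.651, 0.735 and 0.708. Without both sixth libraries the camera adjusted p values were 0.000938 (0.339 with an estimated correlation), 0.82 (0.954) and 0.0347 (0.435). Lists called without them and not with all libraries were septal, preoptic and pallidal neurons at 7.12e-05 (0.339) and ventral striatum markers at 9.76e-05 (0.346), both down, and blood at 0.00146 (0.383), glutamatergic neurons at 0.00751 (0.435) and endothelium at 0.0429 (0.631), all up. Mbp, the myelin basic protein gene, stood at 160 CPM in saline replicate 6, the next lowest saline library at 406. Ttr, the choroid plexus transcript of transthyretin, reached 1710 CPM in oxycodone replicate 6 and 29.9 CPM in the next highest oxycodone library.

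Other ventral lists that camera called were immediate early genes and circadian clock genes, shifted up, and semaphorins and GABA and glycine receptors, shifted down. Their medians were 0.15, 0.13, -0.12 and -0.13, their camera adjusted p values 0.00315, 0.0286, 0.00968 and 0.0488, and their adjusted p values with an estimated correlation 0.708, 0.708, 0.651 and 0.735. Without both sixth libraries the camera adjusted p values were 7.64e-06 (0.346 with an estimated correlation), 0.0429 (0.484), 0.023 (0.346) and 0.000198 (0.346). Cry1, a repressor of the clock, had a log2 change of 0.38 with SE 0.12 and an edgeR adjusted p of 0.462. Sema4g, an axon guidance gene, had 15.9 ± 2.54 CPM in saline and 11.5 ± 2.4 CPM in oxycodone libraries (SD, n = 6 and 6), with an adjusted p of 0.466. Gabra3, a GABA-A receptor subunit, had a log2 change of -0.61 with SE 0.26 and an adjusted p of 0.514, with saline replicate 6 at 118 CPM and the next saline library at 70.3.

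Without both sixth ventral libraries, a choice made after the data had been seen, 0 genes passed in the edgeR fit and 1464 had an unadjusted p under 0.05. Within lane 1 (4 and 4 libraries) and within lane 2 (2 and 2), 0 genes passed.

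**Figure D3:**
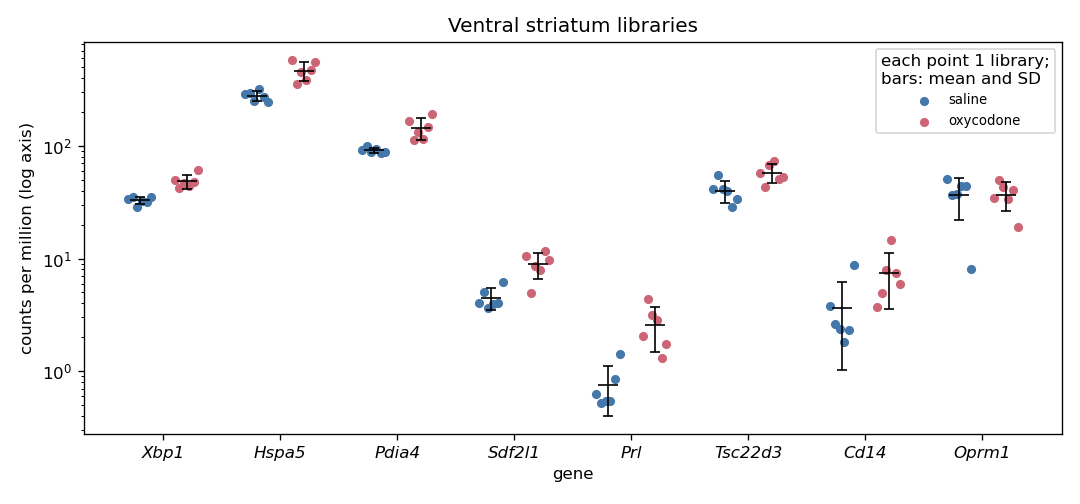
CPM on a log axis of genes named for the ventral striatum, with each point 1 library and the bar the group mean, for 6 saline and 6 oxycodone libraries. Hspa5 averaged 281 CPM in saline and 469 CPM in oxycodone libraries, and no gene shown passed the adjusted threshold in the edgeR fit.

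Opioid and dopamine receptor genes did not pass the threshold of the edgeR fit in either region. Oprm1, the mu opioid receptor gene through which oxycodone acts (ENSMUSG00000000766, chromosome 10, 6758506 to 7038198), had 36.9 ± 15.1 CPM in saline and 37 ± 10.6 CPM in oxycodone ventral libraries (SD, n = 6 and 6). Saline replicate 6 held 8.01 CPM of it and the next lowest saline library 36.5. Leaving out each ventral replicate in turn gave log2 changes of -0.2085 to 0.1315. In dorsal libraries Oprm1 had 19.1 ± 4.06 and 15.5 ± 2.76 CPM (SD, n = 5 and 5), with an edgeR adjusted p of 0.983. Oprl1, the nociceptin receptor gene, had a log2 change of -0.35 with SE 0.14 and an adjusted p of 0.508 in ventral libraries, and of 0.09 with SE 0.16 in dorsal ones. Penk, the enkephalin precursor, had log2 changes of 0.39 with SE 0.45 in ventral and -0.02 with SE 0.08 in dorsal libraries. Its ventral change was 0.147 without saline replicate 6, which held 75.2 CPM, 0.226 without oxycodone replicate 6, which held 1842 CPM, and -0.019 without both. Drd1 and Drd2, the D1 and D2 dopamine receptor genes, had changes of 0.62 with SE 0.51 and 0.72 with SE 0.54 in ventral libraries. Saline replicate 6 held 5.82 and 3.72 CPM of them, and the next lowest saline library 149 and 112. Oxycodone replicate 6 held 338 CPM of Drd2, and the next highest oxycodone library 183. In dorsal libraries the changes of Drd1 and Drd2 were 0.04 with SE 0.07 and -0.15 with SE 0.09.

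Whether oxycodone acted differently in the 2 regions was tested as an interaction. In the edgeR fit 0 of 14938 genes passed, the smallest adjusted p was 0.981, and 674 genes had an unadjusted p under 0.05 against 747 expected. DESeq2 and limma-voom called 0 as well. Htr1f, a serotonin receptor gene, had the lowest p: it stood at 9.3 ± 1.13 and 9.75 ± 2.37 CPM in ventral saline and oxycodone libraries (SD, n = 6 and 6) and at 5.96 ± 2.01 and 2.1 ± 0.784 CPM in dorsal ones (SD, n = 5 and 5). For Xdh and Irf1, called in the dorsal fit and not in the ventral one, the effects differed by 0.48 log2 with SE 0.35 and by 0.48 with SE 0.56, both with an adjusted p of 0.981.

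Across the 13922 genes tested in both regions, the log2 changes after oxycodone had a Pearson correlation of 0.247 and a Spearman correlation of 0.15. Genes are not independent replicates, so labels were permuted within regions: 2 of 100 labellings, the real one included, gave as large a Pearson correlation (permutation p = 0.02), and 5 of 100 as large a Spearman correlation. Permuting each region on its own takes the regions to share no animals, which is not known. Without oxycodone ventral replicate 4 the Pearson correlation was 0.16, with a permutation p of 0.06. That library shares its title number with oxycodone dorsal replicate 5. Their departures from the treatment means correlated by 0.323, the highest of the 10 pairs of libraries sharing a number. An animal common to both regions therefore stays open as a source of the correlation. Without both sixth ventral libraries it was 0.309.

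In the saline libraries, dorsal and ventral striatum differed in 6616 of 14433 genes, 3403 higher and 3213 lower in dorsal libraries. Markers of the dorsal striatum were among them: Reln, the extracellular protein reelin, stood at 848 ± 92.4 CPM in dorsal and 205 ± 21.8 CPM in ventral libraries (SD, n = 5 and 6), and Cnr1 and Coch were 4.6-fold and 6.63-fold higher in dorsal libraries. Calb2, which encodes calretinin and is on the ventral list, had 3.97 ± 2.36 CPM in dorsal and 23.4 ± 7.88 CPM in ventral libraries. Hap1 and Wfs1, on the same list, had log2 changes of -1.88 with SE 0.34 and -1.35 with SE 0.25. Kcnab1, a potassium channel subunit also on the ventral list, went the other way and was 4.42-fold higher in dorsal libraries. The edgeR adjusted p was 0.00114 for Hap1 and smaller for the other 6 of these genes.

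Among the genes given here with a symbol, Ttr, a choroid plexus transcript, had the largest rise in mean level from ventral to dorsal saline libraries. It was 686-fold higher, at 2286 ± 1275 CPM against 3.3 ± 1.64 (SD, n = 5 and 6), and Folr1 and Slc4a5, a folate receptor and a bicarbonate transporter of that tissue, were 57.8-fold and 54.7-fold higher. Rtl8a had 0 counts in every ventral saline library and 2.29 ± 1.08 CPM in dorsal ones, at least 7.04-fold higher against a floor of 3 counts in the smallest ventral saline library. Sinhcaf had 0.0181 ± 0.0442 CPM in ventral libraries, where 1 of the 6 held 1 count and the rest 0, and 5.28 ± 4.01 CPM in dorsal ones. Hist1h4m, a histone gene, was 42.3-fold higher in dorsal libraries. Markers of glutamatergic neurons went both ways: Slc17a6 and Cux2 were lower in dorsal libraries, with log2 changes of -2.27 with SE 0.36 and -2.31 with SE 0.47, and Camkv and Lmo3 were higher, with 1.05 (SE 0.1) and 1.13 (SE 0.19). The edgeR adjusted p was 0.00242 for Cux2, 0.000231 for Lmo3 and 1.04e-06 for Camkv, and region cannot be told apart from library set, since the dorsal and ventral libraries differ in depth and in mitochondrial share. Without saline ventral replicate 6, where Cux2 stood at 213 CPM and the next ventral library at 68.6, 7227 genes passed.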

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

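Values far from the rest of their group were picked out by a set rule, while the tests of explanations here were all chosen after the patterns had been seen, except the test of read mates and the count over other splits. In groups of 5 or 6 libraries, a value stood out when its gap to the nearest library was a large part of the group's range by Dixon's criterion. Of 406 groups of values tested, 80 stood out, and chance picks about 1 in 20. Saline ventral replicate 6 gave 39 of them and oxycodone ventral replicate 6 gave 14. Other libraries gave the rest.

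In saline ventral replicate 6 the total was 11 M counts (M, mega), the highest of its group. List levels that were the lowest of the group, in mean log2 CPM, were 3.13 for the opioid system, 3.62 for the dopamine system, 6.03 for GABA and glycine receptors, 2.78 for D1 and 1.88 for D2 medium spiny neurons, 2.36 for striatal interneurons, 2.24 for septal, preoptic and pallidal neurons, 3.28 for oligodendrocytes, 2.59 for ventral striatum markers and 4.16 for dorsal striatum markers. The highest of the group were 4.79 for microglia and 5.42 for blood. Genes at their lowest there, in CPM, were Mbp at 160, Scn4b at 21.3, Oprm1 at 8.01, Oprk1 at 1.91, Penk at 75.2, Pdyn at 11.3, Drd1 at 5.82, Drd2 at 3.72, Kcnab1 at 42, Hap1 at 93.8, Gpr155 at 63.1 and Camkv at 362. Genes at their highest were Prl at 1.43, Il1b at 1.72, C3 at 10.6, Plxna1 at 255, Cd14 at 8.68, Gabra3 at 118, Ccbe1 at 10, Tmem200a at 31.3, Btbd11 at 30, Folr1 at 0.572, Frzb at 31.4, Tmem215 at 17.6, Coch at 41.9 and Cux2 at 213 CPM.

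In oxycodone ventral replicate 6 mitochondrial genes took 9.25% of the counts and the top 10 genes 10.4%, both the highest of the group. The list level of choroid plexus and ependyma was 3.7 log2 CPM and that of dorsal striatum markers 7.21, both the highest, and that of ventral striatum markers was 3.74, the lowest. Genes at their highest there were Gabrd at 149, Ttr at 1710, Reln at 669, Scn4b at 422, Oprd1 at 19.4, Penk at 1840 and Drd2 at 338 CPM, and Mrnip at 7.48 and Pdyn at 47.1 CPM were at their lowest. Oxycodone replicates 1 and 4 of the ventral striatum each gave 1 value, Armcx5 at 28.8 CPM, the lowest, and Il1b at 7.03 CPM, the highest. In the other ventral saline libraries, the cAMP and MAPK list was lowest in replicate 1 at 6.37 log2 CPM, Tef highest in replicate 2 at 237 CPM, Sinhcaf highest in replicate 3 at 0.108 CPM with the other 5 at 0, and Tmem72 highest in replicate 5 at 0.637 CPM.

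Among dorsal libraries, oxycodone replicate 5 had the highest cytokine list at 3.91 and astrocyte list at 6.94 log2 CPM, and the highest Fcgr4 at 17.9, Itgb2 at 42.8, Ifitm3 at 36.4, Il1b at 13.2, Csf1r at 236 and Alas2 at 97.9 CPM. Oxycodone replicate 1 had the lowest ventral striatum list at 3.23 log2 CPM. Saline replicate 3 had the highest mitochondrial share at 4.12% and top 10 gene share at 5.7%, the lowest list of other neuropeptides and monoamine receptors at 2.8 log2 CPM, and the highest Pdzd2 at 312, S100a8 at 2.31 and Gabrb2 at 212 CPM. Saline replicate 4 had the highest GABA and glycine receptor list at 6.12 log2 CPM, Fcgr4 at 3.02 CPM and Arsj at 0.64 CPM. Saline replicate 2 had the highest fibroblast and meninges list at 3.21 log2 CPM, Fos at 15.4 CPM and Hist1h4m at 35.1 CPM.

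The sixth ventral library of each group stands apart on the marker lists. Low depth is argued against by the smaller of their totals, 9.91 M counts, above the median of 9.285 M of the other 10. A shared shift by lane 2 is argued against for oligodendrocyte genes alone: for 13 of 18 the libraries lie at opposite ends of the 12. That criterion was added when the first test had decided nothing, with 1 of 4 list levels of the other lane 2 libraries outside the lane 1 range. Of the microglia genes, 35% were highest of the 12 in the saline library and 45% in the oxycodone library, so lane 2 otherwise stays open. A candidate explanation for saline replicate 6 is cortical tissue in place of striatum: 71.4% of the glutamatergic genes were higher and 88.9% of the medium spiny neuron genes lower in it than in every other ventral library, and Slc17a7, chosen after its values were seen, reached 1002 CPM. Another 14.3% of the glutamatergic genes were lowest in saline replicate 6, and 73.3% of the fibroblast and meninges genes were highest in it. Oxycodone replicate 6 may hold dorsal striatum, since 73.7% of the dorsal striatum genes were highest in it and its ventral list level of 3.74 lies within the dorsal range of 3.13 to 4.21, although its dorsal list level of 7.21 is below the lowest dorsal library at 7.3 and its mitochondrial share of 9.25% far above theirs; both values were known when that test was written. No biological explanation was tested, and a wrong label or a dissection at another level stays open for both libraries.

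The 29 genes called higher in dorsal oxycodone libraries, among them immune genes, had a median log2 change of 1.26 (median SE 0.25). As many genes were called in 2 of 100 splits of the libraries (30 in the real split, 47 in the highest other). Chance is thus excluded at a share of 0.05 only if the libraries are independent. The splits did not keep the 2 pairs that share a title number together, so they cannot exclude it if each pair came from 1 animal. Against a large rise in the number of microglia alone stand 6 genes of resting microglia, with a median of 0.0992 (-0.27 for P2ry12 to 0.309 for Tmem119). Their distance from 1.26 decides nothing, because the 29 genes were picked by their change in these same libraries. A smaller rise, or more microglia in a changed state, stays open: 15 of the 20 members of the microglia list had a positive log2 change. Residual blood stays open: with the haemoglobin level as a covariate the median was 0.735 (median SE 0.307). Calls ended because the change shrank while its SE grew, haemoglobin being itself higher after oxycodone. Oxycodone replicate 4, a single library, had haemoglobin at 5.87 log2 CPM, within the saline range of 5.39 to 6.19. Its called genes stood at 4.49 against 3.31 to 3.68 in saline libraries, which decides nothing about blood. They were called for being higher in the oxycodone libraries, replicate 4 among them. Oxycodone replicate 5 may carry part of the pattern, since without it the median was 0.932 (median SE 0.239) and 14 genes passed, 7 of them among the 30, and neither value settles how much. The count fell further without other libraries, to 1 without saline replicate 5 and to 9 without oxycodone replicate 2. An effect of oxycodone, the difference that the design names, therefore stays among the open explanations.

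Low counts were mostly even in the dorsal libraries, where 71.8% to 78.7% of the genes with counts of 1 to 20 had an even count, and not in the ventral ones, at 42% to 44.5%. A library added to itself is argued against by odd counts, at least 21.3% of such genes in every dorsal library. Gene models missing from the annotation of 1 region stay open: 0 genes were at 0 in every library of 1 region and at 10 CPM or more in the other, but 2 were at 1 CPM or more, too few to decide, and ENSMUSG00000067833, a gene without a symbol chosen after its values were seen, had 0.0656 CPM in ventral and 161.8 CPM in dorsal saline libraries (another rule for counting or for multi-mapping reads was not tested). Mates of a read pair counted singly may be the source, since for counts of 11 to 20 the even share was still 65.3% to 78.1%, above an even split by its exact 95% binomial (Clopper-Pearson) interval in all 10 libraries and below the share for counts of 1 to 10. No biological explanation was tested, region and way of counting cannot be told apart here, and with the dorsal counts halved 32 genes passed in the dorsal striatum and 6631 between regions.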

How the results depend on the processing

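Tests added after the data had been seen were the sixth ventral libraries left out, dorsal counts halved, the haemoglobin covariate, a fold of at least 2, the fit of 16 libraries without a block, and the check of title numbers. The cause of the changes below was not tested, except where fewer libraries or a looser threshold make it plain. In the ventral striatum 0 genes passed in every edgeR alternative run, against 43 by DESeq2 and 61 by limma-voom, which put 2358 genes at an unadjusted p under 0.05. Leaving out each replicate gave 0 to 0 genes there.

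In the dorsal striatum the 30 genes became 86 by DESeq2, 58 without robust dispersions, 57 at an adjusted p under 0.1, 17 in libraries without the suffix P (3 of them among the 30), 1 in those with it (1), 5 with all 22 libraries in 1 fit (1), of which 2 were higher and 3 lower, and 2 with the haemoglobin covariate (0), both lower. Leaving out each replicate gave 1 to 63 genes: 1 without saline 5 (1 among the 30), 9 without oxycodone 2 (8), 11 without saline 3 (10), 14 without oxycodone 5 (7), 16 without saline 2 (13), 17 without saline 4 (15), 63 without oxycodone 3 (30) and 23 to 26 without 1 of the other 3 libraries. The remaining alternatives, all on the full set of libraries, gave 29 to 45 genes, limma-voom 32 of which 15 were among the 30. Summing the 2 pairs that share a title number, 1 of these alternatives, gave 40 genes, of which 24 were among the 30. Differences between regions in the oxycodone effect stayed at 0 genes under every alternative, 0 to 0 when leaving out replicates. Between regions in saline mice, 1914 genes had a fold of at least 2, and leaving out each replicate gave 5929 to 7227.

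The 12 ventral and 10 dorsal lists both became 0 with an estimated correlation and 0 by fry. Leaving out each replicate gave 9 to 16 ventral and 7 to 10 dorsal lists. The cytokine list in the ventral striatum was called in 3 of 12 such fits, GABA and glycine receptors in 4 of 12 ventral and 5 of 10 dorsal ones, and chaperones in 4 of 10 dorsal ones. The Pearson correlation between regions ran from 0.16 to 0.313, its lowest without oxycodone ventral 4, with a permutation p of 0.06. With each replicate left out, the Spearman correlation was reached by 1 (without saline dorsal 2) to 14 of 100 labellings (without oxycodone ventral 4 or oxycodone dorsal 1). For genes with a mean of at least 10 CPM in both regions, Pearson was 0.252, reached by 2 of 100, and Spearman 0.168, reached by 8.

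Of 1188 dorsal pairs of a named gene and an alternative, 976 kept direction and side of the threshold, 182 lost the call, 17 gained it and 13 reversed. In the ventral striatum 34 of 1211 pairs gained a call, all by DESeq2 or limma-voom, and 15 reversed. All reversals were in genes that were not called. Oprm1 in the ventral striatum was -0.01636 with a surrogate variable, -0.003276 in 1 fit of all 22, -0.06818 in lane 1, -0.08203 without the sixth libraries, -0.01157 on library totals and -0.02492 by limma-voom, and -0.2085 to 0.1315 leaving out replicates. Penk was -0.0696 in lane 1 and -0.01861 without the sixth libraries in ventral libraries, where leaving out replicates gave 0.1467 to 0.5344. It was 0.09475 with the haemoglobin covariate in dorsal libraries, where leaving out replicates gave -0.06394 to 0.04719. Pdyn was -0.04025 in ventral lane 1 (-0.08145 to 0.2479 leaving out replicates), and in dorsal libraries -0.004701 with a surrogate variable, -0.01721 with summed pairs, -0.0074 with the haemoglobin covariate and -0.01407 by limma-voom (-0.02698 to 0.08882). Fos was -0.1735 in ventral lane 2 (0.1411 to 0.3517 leaving out replicates) and -0.1161 with the haemoglobin covariate in dorsal libraries (0.1541 to 0.6905). Drd1 was -0.01714 in dorsal libraries without the suffix P, and -0.004296 to 0.07419 leaving out replicates.

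Title numbers recur in both regions, but the 10 pairs of libraries sharing one correlated by a mean of 0.0412, from -0.0856 to 0.323, the highest in oxycodone ventral 4 with dorsal 5. The mean was reached by 9 of 100 matchings (highest other 0.0679), so whether 1 animal gave both cannot be told apart from chance. With the number as a block 0 genes differed in effect, as without it on the same 16 libraries, and 6317 differed between regions. Weaker changes can be missed: of genes changed 1.5-fold in simulated data, 59.7% were recovered in the ventral and 38.8% in the dorsal design. Simulated genes varied independently, so the shares need not hold for the real libraries.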

Other observations

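The median of the ventral genes below was tested against other splits after its value had been seen, and the lowest camera p of any list and the medians of 2 lists were put to the same test after those lists had been seen to lead. The 29 genes called higher in the dorsal striatum had, in the ventral striatum, a positive log2 change in all 29, with a median of 0.679, and 12 had an unadjusted p under 0.05 there. Irf1 stood at 6.96 ± 2.84 CPM in saline and 17.1 ± 10.7 CPM in oxycodone ventral libraries (SD, n = 6 and 6), with an edgeR adjusted p of 0.449, and Itgal at 1.73 ± 1.31 and 4.42 ± 2.14 CPM with an adjusted p of 0.498. These genes may respond in both regions, but in 9 of 100 splits of the ventral libraries their median difference was as large (0.636 in log2 CPM in the real split, 0.914 in the highest other), so chance is not excluded.

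Genes of resting microglia changed by less than the median of the genes called higher in the dorsal striatum, which says little, since those were picked by their change. P2ry12, a purine receptor of these cells, had a log2 change of -0.27 with SE 0.141, Cx3cr1, their fractalkine receptor, 0.0606 with SE 0.149, and Tmem119 0.309 with SE 0.208. All are from a set of genes chosen after the data had been seen. The endothelium list was not called by camera in either region, at adjusted p values of 0.132 in dorsal and 0.752 in ventral libraries, but was called at 0.0429 (0.631 with an estimated correlation) without both sixth ventral libraries. In dorsal libraries fry's test of change in either direction gave it an adjusted p of 0.0372, with 4 members higher and 1 lower when adjusted over the list alone. That test also gave 0.0372 for the glucocorticoid, blood, cytokine and integrin lists in dorsal libraries and 0.0237 for the chaperone list in ventral ones. The opioid system list was not called, at camera adjusted p values of 0.457 in dorsal and 0.62 in ventral libraries, nor was the dopamine system list, at 0.457 and 0.0736. With all libraries, camera called none of the lists for astrocytes, oligodendrocyte precursors, striatal interneurons, glutamate receptors, ephrins, netrins and slits, or cAMP and MAPK signalling in either region.

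Other splits of the same libraries, 100 with the real one included, show where chance can be excluded. They take every library as independent, which the 2 dorsal pairs that share a title number may not be. Chance is called excluded below only on that assumption. In the ventral striatum the real split had 0 genes past the threshold, which all 100 splits reach by design (highest other 0), so that count says nothing. For its 1289 genes at an unadjusted p under 0.05 chance is not excluded, since 7 of 100 splits had as many, the highest other having 1654. For the dorsal striatum it is excluded for the 30 genes past the threshold, by 2 of 100 splits, and not for the 823 genes at an unadjusted p under 0.05, which 16 of 100 reached (highest other 1494). The difference between regions also had 0 genes, which all 100 reach by design (highest other 1) and which says nothing, while chance is not excluded for its 674 at an unadjusted p under 0.05, reached by 62 (highest other 1664). For the saline regions chance is excluded, by 1 of 100 splits on both counts: 6616 genes past the threshold against 4069 in the highest other, and 7586 at an unadjusted p under 0.05 against 5942.

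Chance is not excluded for the number of lists called, 12 in the ventral striatum, which 41 of 100 splits reached (highest other 20), and 10 in the dorsal, which 10 reached (highest other 12). The median of the chaperone list in the ventral striatum, 0.4009 against 0.3947 in the highest other split, and that of complement and antigen presentation in the dorsal striatum, 1.028 against 0.8989, were each reached by the real split alone (1 of 100). These 2 counts settle nothing, since the lists were picked because they led in the real split. The lowest camera p of any list was taken anew in each split. Its minus log10 was 20.54 in the ventral striatum, reached by 1 of 100 splits (highest other 20.35), and 26.35 in the dorsal, reached by 3 of 100 (highest other 28.36). Both shares lie under 0.05, for a measure added after the leading lists had been seen. The splits were not repeated without the 2 sixth ventral libraries, which lay in opposite groups in the real split. The Pearson correlation of changes between regions, 0.247, was reached by 2 of 100 labellings (highest other 0.257), which take the regions to share no animals. The Spearman correlation, 0.15, was reached by 5 of 100, a share not under 0.05.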
